A study of Mus musculus with 8 samples.

How the data were processed

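Gene expression was measured in 8 samples of mouse bone marrow cells on 1-colour Affymetrix arrays with biotin-labelled cRNA made from 100 ng of total RNA per array. The cells came from C57BL/6 mice that carry a tamoxifen-inducible Cre recombinase at the Rosa26 locus, and they had been transformed with retroviruses for Hoxa9 and for a Meis1 flanked by recombination sites. Per the labels' protocols, the cells grew in Iscove's medium with 10% serum and 5 ng/ml interleukin-3, and 2 µM 4-hydroxytamoxifen was used to delete the Meis1 cDNA, a loss that the submitters checked by genomic PCR. Groups were taken from the labels: 4 arrays of treated, Meis1 deleted cells and 4 arrays of untreated cells with Hoxa9 and Meis1. Nothing in the labels says that the 4 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

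The deposited values are log2 expression values, 1 per probe set and array, judged so from the values themselves, which run from 2.65 to 13.2 with 0 missing. They had been normalized between arrays by the authors, since the 8 deposited columns have nearly the same quantiles, with medians between 4.69 and 4.74. MAS5 is named in the submitters' processing notes, with no version or role. The summarisation method and the genome build are not given in the sources used here, and no coordinates are printed. The probe set names mark perfect-match probes, and no detection calls were used here, so a low level can only be described as near the floor of the table. For arrays, the number per group limits the precision.

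The table held 45141 probe sets, of which 104 were control probe sets and 45037 were not. GEO's platform annotation gave 1 gene symbol to 28898 of these and several symbols to 551, while 15588 were unnamed here. Symbols were checked through gene identifiers against a RefSeq gene table of the GRCm38.p6 assembly, which changed 0 symbols. The design had assumed linear values and an offset. Because the values were already logarithms, they were used as deposited with no offset, as the design also provided for. Offsets of 1 and 64 were tried as alternatives after converting the values back to the linear scale.

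Probe sets in the lowest 40% by mean over the 8 arrays were left out (below log2 4.29), which kept 27022. Among the kept probe sets with 1 symbol, the one with the highest mean stood for its gene, which gave 11836 genes. Among 1061 genes with at least 2 probe sets that passed the test, 60 had such probe sets in opposite directions. Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. All log2 fold changes are Meis1 deleted minus Hoxa9 and Meis1, errors of fold changes are limma's standard errors, and errors of levels are standard deviations over 4 arrays. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, for lists with at least 5 kept genes, with Benjamini-Hochberg adjustment over lists. Controls of RNA quality were compared with a two-sided exact permutation test over 70 assignments, whose smallest p is 0.0286. Python 3.11.15 with matplotlib 3.10.9 drew the plots.

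The tests, the 35 gene lists and the rule for naming genes were fixed before the data were examined. The rule took Meis1 and Hoxa9, the 12 largest rises and the 12 largest falls among genes that passed the test with no overlap between groups and a higher group above the median of the kept probe sets, the 5 rises and 5 falls with the smallest adjusted p, Sytl1, Cxcr4 and Flt3, and up to 4 members of each list with the smallest p. Cxcr4 had no named probe set here. Other genes named below were chosen after their values were seen.

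The procedure was tested on simulated data made from the 11836 genes of this comparison with 4 arrays per group. It recovered 17 of 50 genes changed by 0.25 on the log2 scale, 45 of 50 changed by 0.5, 48 of 50 changed by 1 and 50 of 50 changed by 2, with 4 false calls and 0 sign errors. With no change simulated, 0 genes and 0 lists were called, and a single list raised by 0.5 was called. The simulated genes varied independently of each other, so this does not show how often lists of correlated genes are called falsely. A far smaller share of genes was changed than the 35.5% that passed in the real data. The adjusted threshold was therefore stricter in the simulation, and its recovered shares do not give those of the real comparison. Alternatives covered the offset, quantile normalization, scaling to the 75th percentile, no filter or a filter of 60%, the mean of a gene's probe sets or each probe set alone, eBayes with trend and robust, array weights, the replicate number as a block, each array left out in turn, camera with an estimated correlation, and fry. Fits with an array batch as a block, within each batch, and with both the batch as a block and Meis1 deleted replicate 1 left out were added after seeing the data. Control probe sets were left out of the gene tests, and probe sets with several symbols or none entered no named result.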

Results

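The study compared mouse myeloid cells transformed by Hoxa9 and Meis1 with the same cells after the Meis1 transgene had been deleted. Hoxa9 is a homeobox transcription factor, and Meis1 is a homeobox partner protein that acts with it in acute myeloid leukaemia. The comparison asks which genes depend on the continued presence of Meis1 in cells that keep Hoxa9. It rests on 4 arrays per group, with 11836 genes tested. The drug was given to the deleted group alone, so the effect of 4-hydroxytamoxifen and of Cre activity is contained in every difference below.

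Meis1 itself could not be followed on these arrays. Its kept probe set read 5.02 ± 0.07 (SD, n = 4) in Meis1 deleted cells and 5.00 ± 0.05 in cells with Hoxa9 and Meis1, both above the filter threshold of 4.29 and under the median of 6.42 of the kept probe sets, with a log2 fold change of 0.02 ± 0.05 (SE) and a limma adjusted p of 0.759. A further probe set read 3.78 ± 0.07 and 3.64 ± 0.05 and fell under the filter. Whether either lies within the retroviral cDNA is not given in the sources used here, so these values check neither the deletion nor the labels. Hoxa9 was high in both groups, at 9.74 ± 0.53 and 10.08 ± 0.17, and did not pass the test (log2 fold change -0.34 ± 0.23, adjusted p = 0.292). Meis1 deleted replicate 1 read 8.95 for Hoxa9, and without that array the log2 fold change was -0.07. Whether the Hoxa9 probe set lies within its retroviral cDNA is not given either, so its level does not check that the transgene was kept.

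Treatment to delete Meis1 was followed by a large rise of macrophage and interferon-stimulated genes and by falls of sterol synthesis and glycolysis genes. In all, 4206 genes changed, 2140 higher and 2066 lower, which is 35.5% of those tested. At least 2-fold changes were mostly rises, with 297 genes higher and 80 lower (169 and 32 with an offset of 64), and at least 8-fold changes numbered 41 rises and 2 falls. The largest measured rise was that of Mrc1, the macrophage mannose receptor, from 4.54 ± 0.11 to 10.97 ± 0.15 (log2 fold change 6.43 ± 0.08, adjusted p = 8.69e-11). The largest measured fall was that of Errfi1, a feedback inhibitor of ERBB receptors, from 7.65 ± 0.10 to 3.87 ± 0.10 (log2 fold change -3.78 ± 0.07, adjusted p = 3.48e-10). Some levels, such as those of Errfi1 and Cd34 after the deletion and of Mrc1, C1qa, C1qb and Usp18 in cells with Meis1, lay under the lowest median of an array (4.69), so the sizes and the order of these changes are uncertain.

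The arrays fell into a pair of batches by the spiked bioB hybridisation control, with 3 deleted and 2 control arrays in batch 1 and 1 deleted and 2 control arrays in batch 2. With the batch as a block 4241 genes changed, and 2115 and 2137 changed within batch 1 and batch 2 alone, where fewer arrays were tested and the lone deleted array of batch 2 was assumed to vary like the others. The count of genes changed at least 2-fold was 375 with the block and 378 and 371 within the batches.

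**Figure D1:**
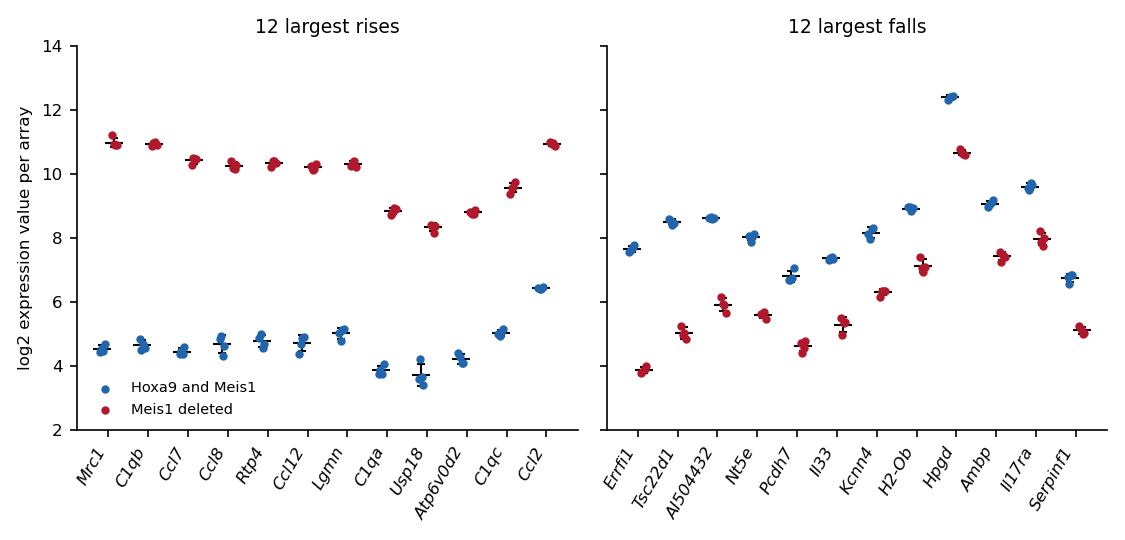
Log2 expression values of the 12 largest rises and the 12 largest falls in each of the 8 arrays, with points for single arrays, horizontal ticks for group means and bars for the standard deviation over 4 arrays. A lack of overlap between the groups was a condition for choosing these genes. Mrc1 moved from 4.54 to 10.97 and Errfi1 from 7.65 to 3.87.

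Genes of monocytes and macrophages rose as a group. Of the 18 measured members, 13 rose and 2 fell, with the same counts when adjusted over the list alone, and the median log2 fold change was 0.82 (camera adjusted p = 4.40e-08). After Mrc1 the strongest were Fcgr1, the high-affinity receptor for immunoglobulin G (3.96 ± 0.06), Gpnmb, a glycoprotein of lysosome-rich macrophages (3.55 ± 0.04), and Msr1, a scavenger receptor (3.10 ± 0.07). Csf1r, the receptor for macrophage colony-stimulating factor, rose by 1.06 ± 0.08 and Trem2 by 2.42 ± 0.09. The members did not all move together: Cd14 fell by 0.41 and F13a1 fell by 0.14, while the monocyte factors Irf8 (-0.06 ± 0.05) and Klf4 (-0.07 ± 0.05) and the chemokine receptor Ccr2 (-0.07 ± 0.08) did not pass. The median was 0.82 with the batch as a block and 0.82 and 0.81 within batches 1 and 2.

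Genes of the first complement component were among the largest rises of all, although no list had been fixed for them: C1qb rose by 6.28 ± 0.07, C1qa by 4.97 ± 0.08 and C1qc by 4.53 ± 0.08 on the log2 scale. The monocyte-attracting chemokines Ccl7 (5.97 ± 0.07), Ccl8 (5.57 ± 0.13), Ccl12 (5.50 ± 0.11) and Ccl2 (4.51 ± 0.05) rose with them. So did Lgmn, a lysosomal protease (5.29 ± 0.09), and Atp6v0d2, a subunit of the vacuolar proton pump (4.60 ± 0.08). Innate receptor genes were called up, with 10 of 16 members higher and 2 lower, the same counts when adjusted over the list alone, and a median of 0.51 (camera adjusted p = 7.63e-04). They included Clec4n (2.62 ± 0.05) and Clec7a (1.11 ± 0.04), receptors for fungal sugars, and the toll-like receptors Tlr7 (2.56 ± 0.06) and Tlr2 (1.00 ± 0.05). The median of this list was 0.26 with an offset of 64, 0.52 with the batch as a block and 0.50 and 0.54 within the batches.

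Syk and ITAM signalling genes were called up with the preset correlation (8 of 16 rose and 2 fell, 9 and 2 when adjusted over the list alone; median 0.26, camera adjusted p = 0.00303). The call was lost with an estimated correlation (adjusted p = 0.146 with an estimated correlation), and the median was 0.17 with the mean of a gene's probe sets. The members that moved most were Fc receptors, Fcgr1, Fcgr4 (1.81 ± 0.05) and Fcgr2b (0.68 ± 0.06), and the adaptor Tyrobp rose by 0.36 ± 0.04.

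Interferon-stimulated genes gave the strongest list result. All 20 measured members rose, over all genes and when adjusted over the list alone, with a median of 2.18 (camera adjusted p = 1.18e-19). Rtp4 rose from 4.76 ± 0.19 to 10.33 ± 0.08, and Usp18, a protease that removes the ubiquitin-like modifier Isg15, rose from 3.71 ± 0.35 to 8.32 ± 0.12. The antiviral genes Ifit2 (4.05 ± 0.12), Oasl2 (3.50 ± 0.07) and Mx1 (2.71 ± 0.08) rose as well. The list's median was 1.26 with an offset of 64, 2.17 with the batch as a block and 2.21 and 2.17 within batches 1 and 2.

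NF-kB and cytokine genes were called up (13 of 19 rose and 2 fell, with the same counts when adjusted over the list alone; median 0.40, camera adjusted p = 4.88e-04), a call lost with an estimated correlation (adjusted p = 0.108 with an estimated correlation). The median was 0.20 with an offset of 64 and 0.25 with no filter. The members that rose most were chemokines, Ccl2, Ccl5 (1.44 ± 0.08), Cxcl2 (1.36 ± 0.06) and Ccl4 (1.14 ± 0.07).

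Late neutrophil genes rose too. Of 19 members 14 rose and 2 fell, 15 and 2 when adjusted over the list alone, with a median of 0.64 (camera adjusted p = 2.40e-08). The secondary granule proteins Ltf (2.58 ± 0.05), Mmp8 (2.00 ± 0.05) and Camp (1.78 ± 0.05) led, followed by Chil3 (1.69 ± 0.05), and Csf3r, the receptor for granulocyte colony-stimulating factor, rose by 1.04 ± 0.08. Within the batches the median was 0.69 and 0.61, and 0.66 with the batch as a block. Primary granule genes, which mark an earlier stage, went both ways: 3 of 10 rose and 4 fell, with the same counts when adjusted over the list alone, and the list was not called. Myeloperoxidase (Mpo) rose by 0.59 ± 0.08 and Ctsc by 0.58 ± 0.05, whereas neutrophil elastase (Elane) fell by 0.50 and Cst7 fell by 0.47.

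Genes linked to Meis1 were called down with the preset correlation. Of the 10 measured members of the list of genes that earlier work ties to Meis1, 7 fell and 2 rose, with the same counts when adjusted over the list alone (median -0.34, camera adjusted p = 0.00461). The call was lost with an estimated correlation (adjusted p = 0.0604 with an estimated correlation) and with the lowest 60% of probe sets left out (adjusted p = 0.202). Cd34, a surface marker of progenitors, fell from 5.87 ± 0.21 to 4.00 ± 0.08, the ETS factor Erg from 6.29 ± 0.08 to 4.94 ± 0.12, and the RNA-binding protein Msi2 from 8.11 ± 0.06 to 7.38 ± 0.16. The cytokine receptor Flt3 fell from 5.78 ± 0.12 to 4.98 ± 0.16 (log2 fold change -0.80 ± 0.09, adjusted p = 1.25e-04). In both groups Cd34, Erg and Flt3 lay under the median of the kept probe sets (6.42), as did Sytl1. Sytl1, a partner of Rab27 in vesicle transport, fell from 5.51 ± 0.07 to 5.11 ± 0.15 (-0.40 ± 0.08, adjusted p = 0.00298). Within batch 1 it read -0.44 (adjusted p = 0.0504) and within batch 2, with 1 deleted array, -0.31 (adjusted p = 0.0970). The list's median was -0.16 with an offset of 64 and -0.19 with no filter or with the lowest 60% left out, and it was -0.33 with the batch as a block and -0.38 and -0.25 within the batches.

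The wider list of stem and progenitor genes was not called. It shares Cd34, Erg, Msi2 and Flt3 with the list of genes linked to Meis1, so their falls count in both. Of 20 members 9 fell and 4 rose, or 10 and 6 when adjusted over the list alone, and Lmo2 was among those that rose (0.59 ± 0.04). Among haematopoietic transcription factors 5 rose and 8 fell of 20, or 7 and 9 when adjusted over the list alone, with no call for the list. Id1 fell by 1.39 and Gfi1b fell by 0.65, while Gfi1 (0.80 ± 0.06) and Id2 (0.73 ± 0.05) rose. Among Hox and TALE genes other than Hoxa9 and Meis1, 3 of 12 rose and 2 fell, with the same counts when adjusted over the list alone and no call. Pbx2 (0.56 ± 0.07) and Hoxb3 (0.40 ± 0.05) rose, and Pknox1, a relative of Meis1, fell by 0.56. Homing and adhesion genes split, with 8 of 17 higher and 7 lower, 9 and 7 when adjusted over the list alone: Vcam1 (0.71 ± 0.10) and Cd9 (0.70 ± 0.05) rose and Itgb7 fell by 1.37. Of 9 Rab27 and exocytosis genes, Myo5a (0.76 ± 0.04) and Vamp8 (0.38 ± 0.04) rose and Sytl1 fell, also when adjusted over the list alone. Neither of these lists was called.

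Among the largest falls outside the lists were Tsc22d1 (-3.47 ± 0.09), the long non-coding RNA gene AI504432 (-2.70 ± 0.09), Nt5e, which makes adenosine at the cell surface (-2.43 ± 0.07), the protocadherin Pcdh7 (-2.18 ± 0.10) and the cytokine Il33 (-2.06 ± 0.10). The calcium-activated potassium channel Kcnn4 fell by 1.87, H2-Ob fell by 1.79, the prostaglandin-degrading enzyme Hpgd fell by 1.73, Ambp fell by 1.65, and Il17ra and Serpinf1 each fell by 1.64. Selenbp2 fell by 1.53 with 1 of the 5 smallest adjusted p among falls (2.81e-08).

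Sterol synthesis genes fell with a single exception. Of 18 measured cholesterol synthesis genes 17 fell and 0 rose, also when adjusted over the list alone, with a median of -0.46 (camera adjusted p = 2.40e-08). The enzyme Cyp51 fell by 1.08, Insig1, a sterol-sensing regulator, fell by 0.85, Sc5d fell by 0.71 and Msmo1 fell by 0.51. Glycolysis and hypoxia genes fell as well: 12 of 20 were lower and 2 higher, 13 and 2 when adjusted over the list alone, with a median of -0.29 (camera adjusted p = 3.52e-05). The hypoxia-responsive Egln3 (-1.34 ± 0.06) and Bnip3 (-1.17 ± 0.05) and the enzymes Pfkp (-0.64 ± 0.04), Pdk1 (-0.58 ± 0.07), Pgk1 (-0.35 ± 0.04) and Ldha (-0.32 ± 0.05) were lower. With the batch as a block the medians of these lists were -0.44 and -0.28. Within batch 1 they were -0.44 and -0.30, and within batch 2 -0.51 and -0.26.

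Unfolded protein and amino acid response genes were not called: 9 of 23 fell and 5 rose, or 9 and 6 when adjusted over the list alone. The amino acid response members Asns (-0.80 ± 0.05), Psat1 (-0.61 ± 0.05) and Atf4 (-0.51 ± 0.05) and the chaperone Dnajb9 (-0.78 ± 0.07) were lower. Oxidative phosphorylation genes rarely changed, with 1 of 29 higher and 2 lower over all genes and 0 in either direction when adjusted over the list alone. Ribosomal protein genes were called down (7 of 26 fell and 0 rose, with the same counts when adjusted over the list alone; median -0.10, camera adjusted p = 3.51e-04), a call lost with an estimated correlation (adjusted p = 0.204 with an estimated correlation). Rpl22 fell by 0.24, Rpl12 fell by 0.19 and Rps9 fell by 0.18. Ribosome biogenesis and Myc target genes were called down (8 of 22 fell and 0 rose, 10 and 0 when adjusted over the list alone; median -0.11, camera adjusted p = 0.0239), also lost with an estimated correlation (adjusted p = 0.162 with an estimated correlation). Ppan fell by 0.49, Dkc1 fell by 0.41, and Myc itself fell by 0.90.

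DNA replication genes fell by small amounts. Of 28 members 12 fell and 1 rose, 13 and 1 when adjusted over the list alone, with a median of -0.13 (camera adjusted p = 7.63e-04; -0.12 with the batch as a block and -0.12 and -0.18 within the batches). E2f2 fell by 1.06, Ccne2 fell by 0.46, Cdc6 fell by 0.31 and Cdc45 fell by 0.26. Mitosis genes were not called, with 5 of 25 higher and 6 lower, or 6 and 7 when adjusted over the list alone. Plk1 (0.51 ± 0.07) and Pttg1 (0.35 ± 0.06) rose, and Nusap1 fell by 0.32 and Mad2l1 fell by 0.30.

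Genes of the p53 response were called up (10 of 18 rose and 2 fell, 11 and 3 when adjusted over the list alone; median 0.35, camera adjusted p = 9.57e-04), a call lost with an estimated correlation (adjusted p = 0.0604 with an estimated correlation). The median was 0.22 with no filter. The kinase Plk2 (2.24 ± 0.12), the RNA-binding Zmat3 (1.62 ± 0.09), Trp53inp1 (1.03 ± 0.04) and Sesn1 (0.75 ± 0.05) rose. Mdm2, the main feedback inhibitor of p53, fell by 0.36, and the cell cycle inhibitor Cdkn1a did not pass (0.36 ± 0.14, adjusted p = 0.0785). With the batch as a block Cdkn1a passed (0.45 ± 0.08, adjusted p = 0.00324). It also passed within batch 1 (0.56, adjusted p = 0.00507), while the adjusted p of 0.0488 within batch 2 (0.41) rests on 1 deleted array. It passed with the mean of probe sets (0.000317), with array weights (0.0105), with the replicate number as a block (0.0103), without Meis1 deleted replicate 1 (0.0197, and 0.000109 with the batch as a block too) and without Hoxa9 and Meis1 replicate 4 (0.0433). BCL2 family and survival genes were called up (9 of 18 rose and 1 fell, 10 and 1 when adjusted over the list alone; median 0.17, camera adjusted p = 0.0203), lost with an estimated correlation (adjusted p = 0.0925 with an estimated correlation) and with the mean of a gene's probe sets (median 0.0944, adjusted p = 0.0770). The survival gene Bcl2a1a rose by 2.90 ± 0.08 and Mcl1, also a survival gene, fell by 0.25.

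Immediate-early and ERK-response genes were not called as a list, though they were called down with the replicate number as a block (adjusted p = 0.0456), without Hoxa9 and Meis1 replicate 4 (adjusted p = 0.0487) and with the batch as a block and Meis1 deleted replicate 1 left out (adjusted p = 0.0382). Of 24 members 5 rose and 11 fell, or 6 and 13 when adjusted over the list alone; Egr2 (2.43 ± 0.07), Atf3 (1.43 ± 0.08) and Fos (1.01 ± 0.08) rose while Fosl2 fell by 1.16. In the interleukin-3 and JAK-STAT list 3 of 14 rose and 7 fell, with the same counts when adjusted over the list alone and no call. Csf2rb2, a receptor subunit for interleukin-3, rose by 1.22 ± 0.07, and Cish, a feedback gene of STAT5, fell by 0.73 and the kinase Jak2 fell by 0.32. Of 8 oestrogen-response genes, included because tamoxifen binds the oestrogen receptor, Ctsd (1.32 ± 0.07) and Igfbp4 (0.63 ± 0.08) rose and 2 fell, with the same counts when adjusted over the list alone and no call.

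Markers of lineages other than neutrophils and macrophages gave no called list. Among 12 megakaryocyte genes 5 rose and 2 fell, with the same counts when adjusted over the list alone: the platelet chemokines Pf4 (3.84 ± 0.06) and Ppbp (3.44 ± 0.09) rose, and the platelet integrin Itga2b did not pass (-0.21 ± 0.09, adjusted p = 0.0961). Without Hoxa9 and Meis1 replicate 1 Itga2b read -0.27 with an adjusted p of 0.0424. Of 8 mast cell and basophil genes 3 rose and 2 fell, also when adjusted over the list alone, with Hpgds (1.54 ± 0.22) and Mitf (0.79 ± 0.06) higher and Mcpt8 lower (-0.74 ± 0.13). In the dendritic cell and MHC class II list 1 of 11 rose and 5 fell, also when adjusted over the list alone; Cd74 rose by 0.57 ± 0.06 and H2-DMa fell by 0.38, a call lost with the mean of its probe sets (-0.0950, adjusted p = 0.231). Thy1 fell by 1.30 as the only change among 6 T and NK cell genes, Fn1 fell by 1.06 among 8 stromal and endothelial genes, of which 1 rose and 2 fell, and 1 of 5 erythroid genes rose and 1 fell. Those counts did not differ when adjusted over the list alone. B cell genes (4 kept, of which 2 rose and 0 fell, also when adjusted over the list alone), eosinophil genes (0 kept) and sex-linked genes (1 kept, 0 changed) were too few to test.

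Of the 32 lists tested, 14 were called, 8 up and 6 down. The 7 that held with an estimated correlation were the interferon-stimulated, monocyte and macrophage, late neutrophil, innate receptor, cholesterol synthesis, glycolysis and hypoxia, and DNA replication genes. Among lists that lost their call, the estimate was under the preset 0.01 for Meis1-linked (-0.06) and BCL2 family genes (-0.04). A higher correlation therefore did not remove those calls, and for the other lists that lost theirs the estimate was above the preset. The median and mean of a list, or its test, differed in sign for the erythroid, oestrogen-response and unfolded protein lists, none of them called.

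**Figure D2:**
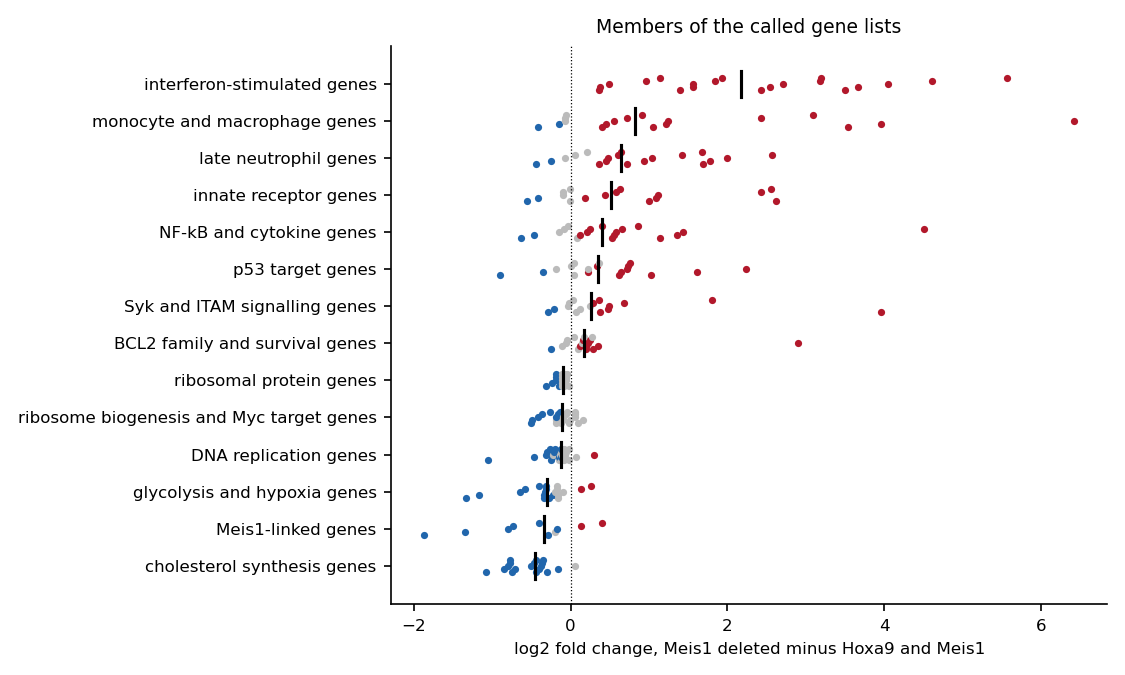
Log2 fold change (Meis1 deleted minus Hoxa9 and Meis1) of each measured member of the 14 called lists, red where a gene rose, blue where it fell and grey where it did not pass, with a vertical bar at each list's median. Medians run from 2.18 for interferon-stimulated genes to -0.46 for cholesterol synthesis genes.

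Signs of RNA quality set a single array apart. In Meis1 deleted replicate 1 the 3' probe set of Gapdh read 0.72 above its 5' probe set on the log2 scale, against -0.07 to 0.04 in the other 7 arrays, and the same difference for Actb was 0.67 against 0.32 to 0.38. Neither difference passed between the groups (exact permutation p = 0.486 for Gapdh and 0.543 for Actb). Without that array 4659 genes changed and 376 did so at least 2-fold. The list medians were then 2.07 for interferon-stimulated genes, 0.72 for monocyte and macrophage genes and -0.52 for cholesterol synthesis genes. In the first principal component, which took 83.6% of the variance, the groups lay apart, and the next took 7.88% and set Meis1 deleted replicate 1 against the rest.

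**Figure D3:**
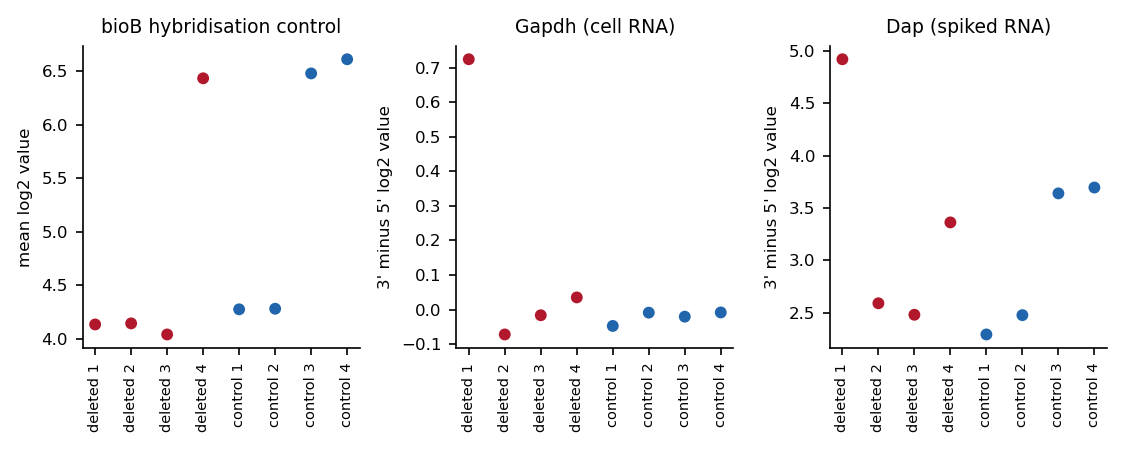
Values of 3 technical measures in each array, with Meis1 deleted arrays in red and Hoxa9 and Meis1 arrays, called control on the axis, in blue: the mean log2 value of the bioB hybridisation control, and the log2 difference of 3' and 5' probe sets of Gapdh and of the spiked Dap control. The bioB values fall at 4.04 to 4.28 in 5 arrays and 6.43 to 6.61 in 3, and Meis1 deleted replicate 1 is highest for Gapdh (0.72) and Dap (4.92).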

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

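The tests of array batch, of labelling, of cell replacement and of drug activity below were chosen after the results were seen, the bound for cell replacement was reset after its value was known, and the splits of the arrays were planned before. In 348 groups of 4 arrays, over named genes and control measures, 21 had an array far from the other 3, and chance alone would give about 17.4. Of these 21, 10 were in Meis1 deleted replicate 1.

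Meis1 deleted replicate 1 stood apart in 8 named genes and in a pair of control measures. It was lowest of its group for Hoxa9 (8.95), Kcnn4 (6.15), Mmp8 (10.69), Mitf (8.92) and Gar1 (9.36), and highest for Mrc1 (11.19), Pknox1 (7.82) and Chil3 (12.27). Its 3' minus 5' difference was highest for Gapdh (0.72) and for the spiked Phe control (3.20). Other arrays set apart in their group were Meis1 deleted replicate 3, lowest for Usp18 (8.13) and Ccl4 (8.33), and Meis1 deleted replicate 4, lowest for Cd34 (3.88) and Ifit2 (8.86) and highest for the bioB control (6.43). Among arrays with Hoxa9 and Meis1, replicate 4 was highest for Pcdh7 (7.04), Rpl22 (11.70) and Ctsl (10.80), replicate 1 was lowest for Msi2 (8.01) and Cd74 (5.87), and replicate 2 was lowest for Mcpt8 (7.62). A signal also lay in probe sets that entered no named result. Of the 8273 kept probe sets without a single gene symbol here, 156 changed at least 2-fold (limma, adjusted over those probe sets).

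The distance of Meis1 deleted replicate 1 may come from loss of 5' ends during labelling. Its 3' minus 5' difference was the highest of its batch for 4 of the 4 spiked bacterial RNAs as well as for Gapdh and Actb. Degraded cell RNA alone is argued against by the spiked Dap RNA, which never was in the cells and read 4.92 there against 2.29 to 2.59 in the other arrays of its batch. The design names no biological difference between this array and the rest of its group, so none was tested.

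The rise of monocyte and macrophage genes did not depend on the array batch, since the lowest list median with the batch as a block or within a batch was 0.81. Poor labelling of Meis1 deleted replicate 1 is argued against in the same way, with a median of 0.72 without that array. Replacement of most cells by mature macrophages would lower primary granule transcripts by 1 or more (log2) if other cells kept their levels. The 4 such genes with a mean level under 12 (Cst7, Mpo, Elane and Nkg7) had a median of -0.37 (standard deviation 0.51). The lowest, Elane, read -0.50 ± 0.13. Mpo and the late neutrophil list rose, so levels in other cells may have changed, and these 4 genes cannot decide the question. F13a1 of the macrophage list and the lysosome gene Ctsb read 12.23 and 10.32 with Meis1 and 12.08 and 12.28 without. Mrc1 (4.54 to 10.97), C1qb (4.64 to 10.93) and Mertk (4.38 to 8.40) rose from under the lowest median of an array (4.69). Of the 18 measured list members 13 rose and 2, F13a1 among them, fell. Replacement of nearly all cells is argued against by the primary granule list, whose 10 genes had a median of 0.002 (3 rose, 4 fell). After the deletion Mpo read 10.89 and Elane 10.80, above the median of the kept probe sets (6.42). A smaller share of such cells was not tested, and replacement of part of the cells stays open. An effect of Meis1 loss stays a hypothesis, as the design ties it to the drug.

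The rise of interferon-stimulated genes was kept within array batches, with a lowest median of 2.17, and without Meis1 deleted replicate 1, with a median of 2.07, so neither accounts for it. A response to Cre activity or to the drug, in place of the loss of Meis1, cannot be told apart: 0 arrays had the drug with Meis1 kept, or lacked Meis1 without the drug. Both therefore stay open beside a biological effect of Meis1.

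Among the splits of the arrays the real one gave the highest count each time, which is the strongest result this test can give. Every other split mixes deleted and control arrays, so the difference between the groups widens its spread, and its count is no measure of chance. Chance differences between cultures stay open, since the samples of a group may be technical. Of the 35 splits of the 8 arrays into groups of 4, 1 gave as many changed genes as the real split, which was the real split itself with 4206, and the highest other gave 0. For genes changed at least 2-fold 1 split reached the real 377 and the highest other gave 0. For called gene lists 1 split, the real one, reached 14, but only narrowly. The highest other, which grouped Meis1 deleted replicate 1 with 3 arrays of the other group, gave 13. The real split also gave 13 with the lowest 60% of probe sets left out or with the mean of probe sets. For this count chance is therefore not excluded.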

How the results depend on the processing

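The batch fits were chosen after seeing the data, and the other alternatives were planned. In leave-one-out fits the counts ran from 3430 to 4659 changed genes, 373 to 381 genes changed at least 2-fold and 14 to 15 called lists. The replicate number as a block gave 3906 changed genes, and the numbers do not pair the arrays, as same-numbered arrays had correlations of 0.03, 0.22, -0.13 and 0.29 between their deviations. Per probe set, with more features tested, 8450 changed (3831 higher, 4619 lower) and 668 at least 2-fold (499 higher, 169 lower). Within array batch 1, with 5 arrays, 2115 genes changed (1220 higher, 895 lower), and within array batch 2, with 3 arrays and the lone deleted array assumed to vary like the others, 2137 (1146 higher, 991 lower); of these, 2082 and 2029 were among the 4206. Leaving out Meis1 deleted replicate 1 with the batch as a block gave 5395. An offset of 64, which shrinks folds of low values, left 201 genes at least 2-fold (169 higher, 32 lower). An estimated correlation called 7 lists and fry, which does not compare a list with other genes, called 27; the other settings gave 13 to 15.

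The near-zero difference of Meis1 reversed within array batch 1 (-0.0129), and that of Hoxa9 within array batch 2 (0.0498). Ccr2 reversed with the mean of probe sets (0.10), within batch 2 (0.0206) and without Meis1 deleted replicate 1 with the batch as a block (0.0134), and ranged from -0.112 to 0.00367 in leave-one-out fits, highest without Meis1 deleted replicate 1. Irf4, at -0.65 over all arrays with a mean of 4.24 in Meis1 deleted cells, ranged from -0.669 to 0.0774 in leave-one-out fits, with 0.0774, 0.0533 and 0.0647 without Hoxa9 and Meis1 replicates 1, 2 and 4, and read 0.0426 within batch 1. In these 4 fits another of its probe sets had the higher mean and stood for the gene. Rpl13 read 0.0454 with the mean of probe sets. It was among the 60 genes whose probe sets that passed went in opposite directions, and the mean mixes them. For Meis1, Hoxa9 and Ccr2 the cause was not tested. Of 3637 values of named genes, 3543 kept their direction and their side of the threshold, 73 lost their call, 10 gained one and 11 reversed; of 360 list values 348, 9, 3 and 0 did so. Signal near the floor of the table limits what can be said of low genes.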

Other observations

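The 4 lists of this part were written after the leading genes were seen but before the lists themselves were tested. The genes that had prompted a list were left out of its test, and for BMP and TGF-beta feedback Smad7 was left out, and the rule for that test changed, only after its results had been seen. Lists fixed earlier also held 0 of the lysosome genes, 2 of the clearance genes, 1 of the antigen processing genes and 3 of the BMP and TGF-beta feedback genes. Lysosome genes rose widely. Of 28 measured genes 25 rose and 0 fell, with the same counts when adjusted over the list alone and a median log2 fold change of 0.42. They included the cathepsins Ctsl (1.37 ± 0.04) and Ctsk (1.31 ± 0.05) and the lysosomal lipase Lipa (1.26 ± 0.05). Genes for the clearance of apoptotic cells rose in part: of 20 measured, 9 rose and 1 fell, also when adjusted over the list alone, with the bridging proteins Gas6 (2.99 ± 0.08) and Mfge8 (2.32 ± 0.10) far ahead. The receptor that Gas6 binds, Mertk, had prompted the list and rose by 4.02 ± 0.07.

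Antigen processing genes rose by smaller amounts. Of 16 measured, 10 rose and 0 fell, 11 and 0 when adjusted over the list alone, with a median of 0.30. Nlrc5, a regulator of MHC class I genes, rose by 0.92 ± 0.06 and the class I gene H2-K1 by 0.28 ± 0.05. Psmb10 rose by 0.36 ± 0.06, while Psmb8 (-0.11 ± 0.07) and Psmb9 (-0.03 ± 0.04) did not pass. BMP and TGF-beta feedback genes fell in few members: 2 of 10 fell and 1 rose, also when adjusted over the list alone. The SMAD repressor Skil fell by 1.29 and its relative Ski fell by 0.96, while Bambi rose by 0.36 ± 0.05. Smad7, an inhibitor of TGF-beta signalling that had prompted this list, fell by 1.60.

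As hypotheses, a wider rise of lysosome genes may go with that of Ctsb, Ctsd, Lgmn, Gpnmb and Atp6v0d2 (camera p = 1.28e-13 with the preset and 4.00e-04 with an estimated correlation). A wider rise of clearance genes may go with that of the C1q genes and Mertk (camera p = 4.23e-04 with the preset and 0.00849 with an estimated correlation). A rise of antigen processing genes may go with that of interferon-stimulated genes (camera p = 1.56e-05 with the preset and 0.00356 with an estimated correlation). For a wider fall of BMP and TGF-beta feedback genes with Id1 and Smad7 the test gave no call (camera p = 0.138 with the preset and 0.173 with an estimated correlation), and with 10 measured genes that go both ways a small fall of the list and none cannot be told apart. With Smad7 kept in that list, as first run, the preset correlation gave a camera p of 0.0341. Adjusted over the 4 lists, the preset values were 5.12e-13, 5.63e-04, 3.11e-05 and 0.138 in the order given.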
